A study of Mus musculus with 12 samples.

How the data were processed

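The series measured 5-hydroxymethylcytosine (5hmC), the oxidised form of 5-methylcytosine that Tet enzymes make, in genomic DNA of mouse embryonic stem cells (ESC, the EB5 line, cultured with LIF) and of heart and liver. Per the labels' protocols, DNA was purified with an RNase step, 5hmC was tagged with an azide-bearing glucose by the beta-glucosyltransferase of phage T4, biotin was coupled to the tag, and tagged fragments were captured on streptavidin and sequenced. Reads from such a pull-down grow with the 5hmC of a region and also with its number of CpG sites and the ease of sequencing it, and no library of unenriched DNA was used here. A level is therefore relative to the other regions and libraries, and is not a share of cytosines.

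Heart and liver came from embryonic day 14 (E14), from newborns of day 1 to 2 (P1) and from adults of 8 weeks (W8). Per the labels, the 12 libraries fall into 7 groups, with 2 libraries each for ESC, P1 heart, P1 liver, W8 heart and W8 liver and 1 each for E14 heart and E14 liver. The labels do not say that replicates came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. ESC and P1 libraries were read from both ends at 75 bp and E14 and W8 libraries from 1 end at 50 bp, per the labels. Read format thus goes with age, and W8 against P1 cannot be separated from it. ESC are of the 129/Ola strain and the tissues of C57BL6/j, so strain goes with ESC against tissue.

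Reads were aligned to the mm9 assembly with Bowtie2, per the submitters' processing notes; the version of Bowtie2 and the read counter are not given in the sources used here. Each library had 1 table of 13581 genes with 1 entry per gene. Per the file headers, the authors deposited FPKM values (depth- and length-scaled read counts) for a promoter window of 4000 bp and for the gene body, with start and end in mm9. The tables name no chromosome. Their lengths equal end minus start, so starts were taken to count from 0 and are printed here from 1. Gene bodies, which hold both exons and introns, were chosen as the main measurement after the columns were seen, because they hold more reads; promoter windows served as an alternative. Each table's 2 FPKM columns were used, leaving 0 columns of per-sample values unused.

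The steps between low FPKM values showed that the authors counted whole reads. In the paired-end libraries 100% of low promoter values were whole multiples of 1 read, within 0.01 reads. Single-end libraries had 2 step sizes, with a ratio of 1.03, and 100% of low promoter values were sums of whole steps. Depth was recovered this way, in single-end libraries from the mean over both steps and so approximately. Reads over gene bodies came to 1131460 and 2112890 in ESC, 767590 and 611469 in P1 heart, 604012 and 2085600 in P1 liver, 3815890 in E14 heart, 5763000 in E14 liver, 3395880 and 142807 in W8 heart, and 4594390 and 4208230 in W8 liver. The counting error of the median gene body was 44.5% of its value in W8 heart replicate 2 and 6.95% to 22.9% in the other libraries. Reads carry no molecular identifiers, so such errors cover counting only. A group listed at 0 was given a floor of 3 reads over the group, and a fold against it is stated as at least that. The mean of the other group was taken as exact, so its own counting error could put the fold lower.

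The design had been written before the data were examined for either counts or normalized values; the branch for normalized values was used. Values were taken as log2(FPKM + 0.0746), the pseudocount being the median non-zero value divided by 10, so fold changes of low genes are understated. Of the genes, 23 had no coordinates and 9 had bodies of length 0 or less; those with a mean of at least 0.0809 FPKM over all libraries were kept, which left 13484. limma 3.58.1 in R 4.3.3 fitted 7 group means to all 12 libraries with 5 residual degrees of freedom and moderated variances with a trend on the mean. P-values were adjusted by the method of Benjamini and Hochberg at 0.05 within each of 9 comparisons. No scaling beyond that of the authors was applied. E14 libraries, which have no replicate, were assumed to vary like the others, and heart against liver at E14 was described without a test.

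A set of 19 gene lists was fixed before the data were examined: cardiac sarcomere, cardiac ion channels and calcium handling, cardiac transcription factors, hepatocyte plasma proteins, hepatocyte metabolic enzymes and transporters, hepatocyte transcription factors, pluripotency, erythroid and haematopoietic, fetal growth and imprinted, fatty acid oxidation, cell cycle, DNA methylation machinery, Hox clusters, markers of endothelium, fibroblasts, macrophages, lymphocytes and of stellate and bile duct cells, and a neuronal control list. Each was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Of 171 such tests 90 passed, and with an estimated correlation 1 did, so each list's adjusted p with an estimated correlation stands beside it. Members are also counted adjusted over the list alone. The neuronal control list itself passed at the preset correlation in several comparisons, so a pass there is not particular to a tissue's genes. A list's median log2 difference is given less that of all genes, unless it is called the list's own. Several genes stand in more than 1 kind of tissue: fatty acid oxidation genes are used by heart and liver, and Gata4 and Gata6 also act in liver.

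The rule for named genes was fixed beforehand: per comparison, the 5 highest and the 5 lowest log2 differences among genes past the threshold with no overlap between libraries and a mean at or above the median gene, up to 3 members of each list by adjusted p, and a set of well-known genes of heart, liver, ESC and 5hmC. Genes outside it are said to be chosen after their values were seen. Some genes that the rule selects are not reported here.

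Replicates were compared before averaging. A chi-square of recovered reads per gene was 1.15 in ESC, 1.04 in P1 heart, 1.06 in P1 liver, 2.56 in W8 heart and 1.47 in W8 liver, with 0 genes identical by value throughout a pair, and each pair differed by more than sampling noise. The fit was tested on simulated data with 200 changed genes among about as many as were measured. Changes of 1.5 and 2 fold were recovered for 0 of 200 genes in each comparison. The adjustment is stricter when few genes change, and the measured comparisons called up to 4151 genes. Some differences under 2 fold passed there, so the 0 does not show that such changes go undetected. Changes of 4 fold were recovered for 119 in heart against liver at P1, 110 at W8, 131 in P1 heart against ESC, 108 in P1 liver against ESC, 73 in W8 against E14 heart, 58 in W8 against E14 liver, 122 in W8 against P1 heart, 108 in W8 against P1 liver, and 27 in the tissue by age interaction, with 0 in the wrong direction and 0 to 21 unchanged genes called.

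Alternatives covered the pseudocount, the filter, 2 rescalings of the libraries, a fit to the compared groups alone and a replicate block. Others left out each replicate, or genes on X and Y (chromosomes from a GRCm38 table that matched 13559 genes, used for nothing else). A 1.5-fold minimum was set on the differences as fitted, and also on differences corrected for gene length. Chosen after seeing the data were voom weights on the recovered reads, array quality weights, bodies of at least 5000 bp, promoter windows, and a shared fit without W8 heart replicate 2. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.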

Results

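5hmC was profiled in 12 libraries of mouse ESC, heart and liver, and is given as the FPKM of each gene body. The median gene body held 19 to 207 reads in 11 libraries and 5.04 in W8 heart replicate 2, in which 9.94% of bodies had no read. Over the 1971 bodies of 100 kb or more, where counting noise is small, replicates correlated across genes at r = 0.990 in ESC, 0.984 in P1 heart, 0.988 in P1 liver and 0.997 in W8 liver. In W8 heart r was 0.871. Genes are not independent replicates. The first 2 principal components of the 2000 most variable genes took 44.8% and 17.2% of the variance. W8 heart replicate 2 stood at -109 on the first, where no other library lay below -6.89. It was doubted for these reasons, and each gene-body count over all genes is also given without it. Fits without W8 heart replicate 1 leave this doubted library alone as W8 heart. They also take the spread between the W8 heart replicates out of the shared estimate, so their counts do not measure a heart effect.

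**Figure D1:**
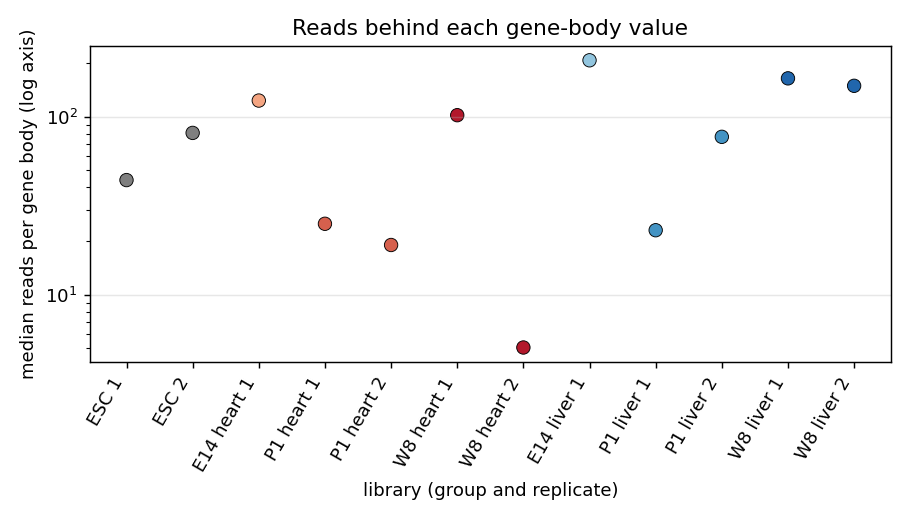
Median number of reads per gene body (y axis, log scale) in each library (x axis, named by group and replicate; colours mark groups). W8 heart replicate 2 lies at 5.04 and the other libraries between 19 and 207.

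The comparison of heart with liver at P1 asked which gene bodies differed in 5hmC between newborn tissues read in the same format. Ttn, which encodes the sarcomere protein titin, was at 1.79 ± 0.0164 FPKM (SD, n = 2) in P1 heart and 0.297 ± 0.0146 in P1 liver over its body from 76542041 to 76818604 (mm9). The log2 difference was 2.33 ± 0.38 (SE, limma, adjusted p = 0.0452). Tbx5 and Hey2, transcription factors of the developing heart, were higher in heart by 1.82 ± 0.25 and 2.49 ± 0.43. Myocd, a cofactor of serum response factor, was higher by 1.82 ± 0.31. Cps1, which starts the urea cycle, was at 0.247 ± 0.00584 FPKM in P1 heart and 0.889 ± 0.0828 in P1 liver over its body from 67171600 to 67277833 (log2 difference -1.58 ± 0.17, adjusted p = 0.0289). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -3.06 ± 0.46, G6pc, the catalytic subunit of glucose-6-phosphatase, by -2.20 ± 0.32, and Hnf4a, a nuclear receptor of hepatocytes, by -1.86 ± 0.34.

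Among the cardiac lists at P1, 3 of 22 measured sarcomere genes were higher in heart and 19 did not pass (13 higher when adjusted over the list alone), with a list median 1.21 above that of all genes. Besides Ttn these were Actn2, the alpha-actinin of the Z disc (1.17 ± 0.17), and Myoz2, which binds it (1.15 ± 0.20). The camera test gave an adjusted p = 2.03e-12, and an adjusted p = 0.0681 with an estimated correlation. Ryr2, the calcium release channel of the sarcoplasmic reticulum (1.71 ± 0.27), was the member past the threshold among 22 ion channel and calcium handling genes (16 adjusted over the list alone). Their median lay 1.28 above all genes (adjusted p = 6.25e-16, and adjusted p = 0.130 with an estimated correlation). Of 20 cardiac transcription factors 3 were higher (8 adjusted over the list alone), with a median of 0.79 (adjusted p = 1.72e-08, and adjusted p = 0.130 with an estimated correlation). Gata4, which acts in both tissues, did not pass at P1 (0.08 ± 0.14, adjusted p = 0.764). In the fit without W8 heart replicate 2, which is in neither group, 13 sarcomere, 16 ion channel and 10 cardiac transcription factor genes were higher, and after median centring 4, 3 and 4.

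On the liver side at P1, 5 of 25 plasma protein genes were lower in heart (18 adjusted over the list alone), among them Itih3, an inter-alpha-trypsin inhibitor chain (-1.74 ± 0.18), and Serpinc1, which encodes antithrombin (-1.18 ± 0.16). Their median lay -1.26 from that of all genes (adjusted p = 2.09e-08, and adjusted p = 0.160 with an estimated correlation). Of 28 metabolic enzymes and transporters 7 were lower (20 adjusted over the list alone), including Ass1 of the urea cycle (-1.48 ± 0.16), with a median of -0.93 (adjusted p = 2.03e-08, and adjusted p = 0.0681 with an estimated correlation). Of 19 hepatocyte transcription factors 2 were lower, Hnf4a and the bile acid receptor Nr1h4 (-0.96 ± 0.17), and 9 adjusted over the list alone (0 after median centring). The median was -0.73 (adjusted p = 0.000352, and adjusted p = 0.151 with an estimated correlation). Fibroblast markers, 0 of 18 past the threshold, had a median of 0.49 (adjusted p = 0.00116, and adjusted p = 0.271 with an estimated correlation). The neuronal control list, 0 of 21, had one of 0.30 (adjusted p = 0.0267, and adjusted p = 0.411 with an estimated correlation). The other 11 lists did not pass. In the fit without W8 heart replicate 2, 19 plasma protein, 22 metabolic and 12 hepatocyte transcription factor genes were lower, and fibroblast and neuronal lists each had 4 higher and 1 lower. The cell cycle list passed then too (adjusted p = 0.0312). After median centring 3 plasma protein and 5 metabolic genes were lower. Past the threshold in the unscaled fit, from lists that did not pass, were Meg3, an imprinted noncoding RNA (-1.14 ± 0.20), and Uhrf1, the partner of Dnmt1 (-1.26 ± 0.22). So was Fabp3, a fatty acid binding protein of heart, which was higher in heart (1.74 ± 0.25). Zcchc3 and Ppp1r14a were listed at 0 in both P1 heart libraries, at least 2.86-fold and 3.75-fold below P1 liver.

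Over all 13484 genes 47 were higher and 260 lower in P1 heart than in P1 liver. Without W8 heart replicate 2, which enters through the shared spread, these were 796 and 2225. The median gene differed by -0.23, and median centring of the libraries turned the split to 95 higher and 52 lower. A replicate block left 5 genes past the threshold, and a fit to the P1 heart and liver libraries alone left 0. Leaving out P1 heart replicate 1 left 46 genes past the limma test. Leaving out P1 heart replicate 2, P1 liver replicate 1 or P1 liver replicate 2 left 0.

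**Figure D2:**
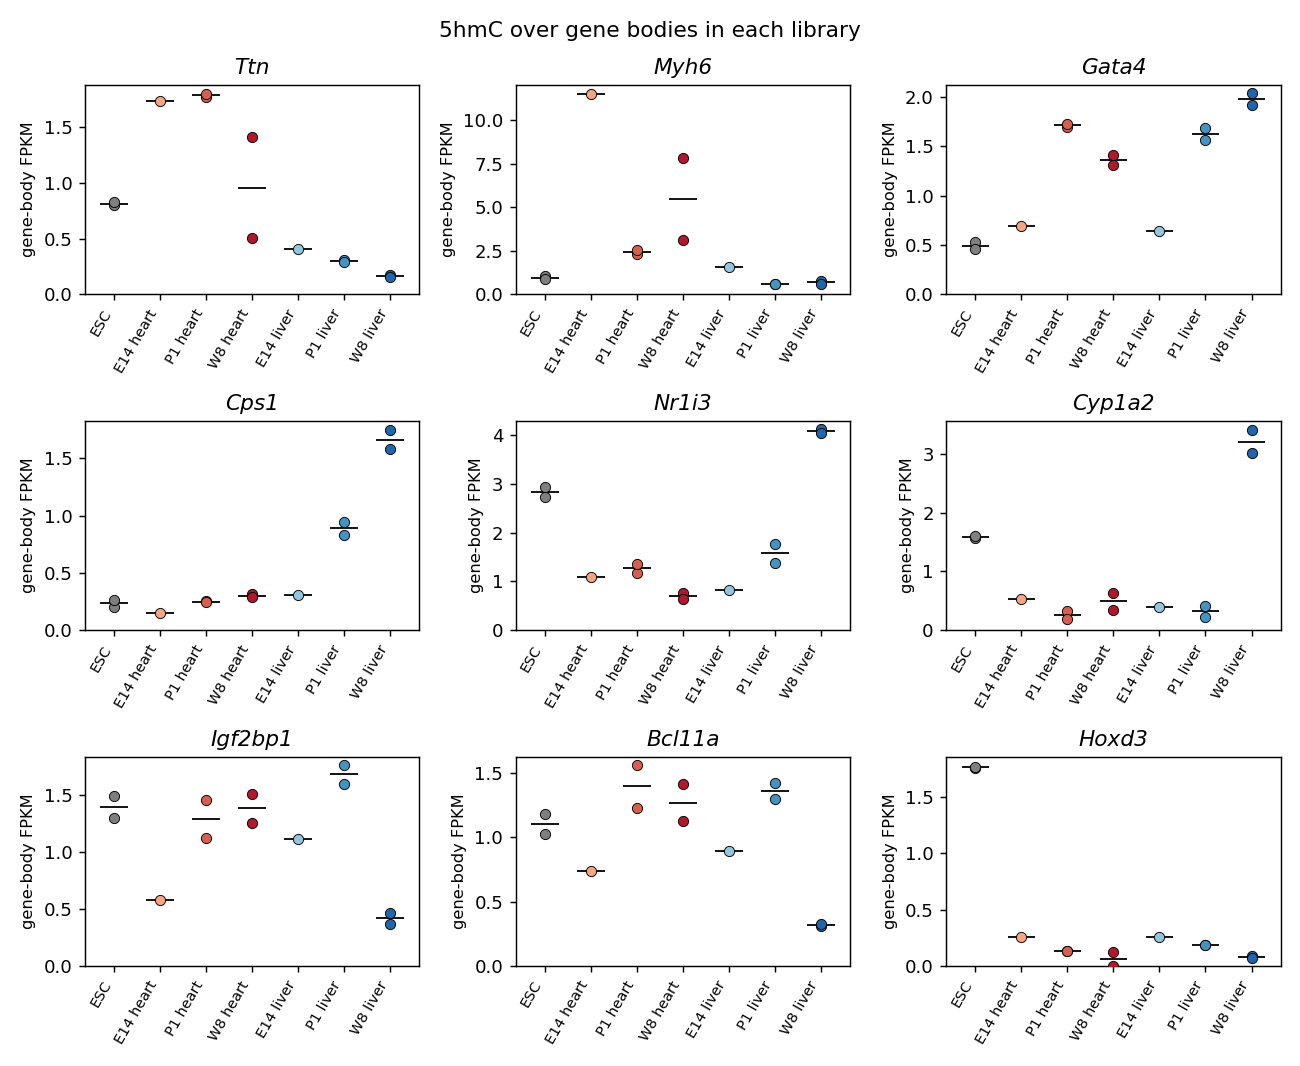
Gene-body 5hmC (y axis, FPKM, from 0) of 9 genes in each group (x axis). Points are libraries and bars are group means. Nr1i3 and Cyp1a2 stood at 4.09 and 3.21 FPKM in W8 liver, above the other tissue groups, and Igf2bp1 and Bcl11a at 0.420 and 0.318, below them.

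At W8 the question of heart against liver was asked in the adult. Nr1i3, the constitutive androstane receptor of hepatocytes, was at 0.700 ± 0.0841 FPKM (SD, n = 2) in W8 heart and 4.09 ± 0.0508 in W8 liver. The log2 difference was -2.43 ± 0.18 (SE, limma, adjusted p = 0.00349). Cps1 and Ass1 of the urea cycle differed by -2.21 ± 0.17 and -2.06 ± 0.16. Cyp27a1, a sterol hydroxylase of bile acid synthesis, differed by -1.73 ± 0.17, and Ppara, a nuclear receptor of lipid catabolism, by -1.65 ± 0.14. Myh6, the alpha myosin heavy chain, was at 5.47 ± 3.34 FPKM in W8 heart and 0.689 ± 0.114 in W8 liver (2.72 ± 0.39, adjusted p = 0.00621; 2.07 without W8 heart replicate 2). Actn2 was higher in heart by 1.91 ± 0.17. So were Kcnh2, a potassium channel of repolarisation, by 1.68 ± 0.17, and Mef2c, a muscle transcription factor, by 1.56 ± 0.16. Gata4 was lower in heart by a small margin (-0.52 ± 0.14).

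Cardiac lists were again higher in heart. Of 22 sarcomere genes 12 were higher (16 adjusted over the list alone; 17 without W8 heart replicate 2), with a median 1.40 above all genes (adjusted p = 2.74e-09, and adjusted p = 0.0942 with an estimated correlation). Of 22 ion channel genes 13 were higher and 1 lower (16 and 1 adjusted over the list alone), with 1.23 (adjusted p = 2.13e-09, and adjusted p = 0.142 with an estimated correlation). Of 20 cardiac transcription factors 6 were higher and 1 lower, equally so adjusted over the list alone, with a median of 0.42 (adjusted p = 0.0121, and adjusted p = 0.271 with an estimated correlation). With the member at 0 in a group set to its floor, the list's own median went from 0.10 to 0.59. Liver lists were lower in heart. Lower were 25 of 28 metabolic enzymes and transporters (27 adjusted over the list alone; 26 without W8 heart replicate 2), with a median of -1.47 (adjusted p = 2.13e-09, and adjusted p = 0.0532 with an estimated correlation). Plasma proteins were lower for 14 of 25 (14 adjusted over the list alone), with -1.06 (adjusted p = 0.0071, and adjusted p = 0.294 with an estimated correlation), and hepatocyte transcription factors for 10 of 19 (11 adjusted over the list alone), with -1.12 (adjusted p = 0.000629, and adjusted p = 0.126 with an estimated correlation). Fatty acid oxidation genes were lower in heart for 19 of 28 (19 lower and 1 higher adjusted over the list alone), including Cpt1a, the liver carnitine palmitoyltransferase (-1.46 ± 0.19), Mlycd (-1.54 ± 0.23) and Hadhb (-0.97 ± 0.16). Their median was -0.53 (adjusted p = 0.000596, and adjusted p = 0.0945 with an estimated correlation).

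Lists of other cell types and of fetal genes were higher in adult heart than in adult liver. Fibroblast markers were higher for 9 of 18 (10 adjusted over the list alone), including the collagen genes Col1a1 (1.75 ± 0.19) and Col5a1 (1.61 ± 0.18), with a median of 0.97 (adjusted p = 6.9e-06, and adjusted p = 0.135 with an estimated correlation). Fetal growth and imprinted genes were higher for 6 and lower for 1 of 20 (11 and 1 adjusted over the list alone), including the RNA binding protein Igf2bp1 (1.56 ± 0.19) and the chromatin protein Hmga2 (1.00 ± 0.15). That list's median was 0.89 (adjusted p = 6.15e-06, and adjusted p = 0.0945 with an estimated correlation). Among 23 erythroid genes 5 were higher and 2 lower, with Bcl11a, a repressor of fetal globin, at 1.76 ± 0.18. Here the median was 0.47 (adjusted p = 0.0071, and adjusted p = 0.216 with an estimated correlation; 0.123 without W8 heart replicate 2). Stellate and bile duct markers (4 higher and 1 lower of 16), endothelial (6 of 18), lymphocyte (4 of 15) and macrophage markers (3 of 16) had medians 0.87, 0.57, 0.56 and 0.44 above all genes. Their own medians were 0.55, 0.25, 0.24 and 0.11. For these lists camera gave adjusted p = 0.00163, 0.00696, 0.0174 and 0.0121 and, with an estimated correlation, adjusted p = 0.0942, 0.225, 0.143 and 0.120. Their counts adjusted over the list alone were 5 and 1, 6, 4 and 2. The neuronal control list (3 higher and 1 lower of 21; 3 and 0 adjusted over the list alone) had a median of 0.45 (adjusted p = 0.0071, and adjusted p = 0.245 with an estimated correlation). The cell cycle list, 0 of 29, had one of 0.39 (adjusted p = 0.0137, and adjusted p = 0.150 with an estimated correlation; 0.0827 without W8 heart replicate 2). The own median of the cell cycle list was 0.07. With the control among them, 16 of 19 lists passed at the preset correlation, so passing was not particular to certain lists. Pluripotency, DNA methylation machinery and Hox lists did not pass, but the pluripotency list did without W8 heart replicate 2 (adjusted p = 0.0109). Higher members then numbered 9 among cardiac transcription factors, 10 in the fetal growth, 7 in the lymphocyte and 6 in the neuronal list. After median centring 9 plasma protein and 11 fatty acid oxidation genes were lower, and 13 fetal growth, 7 stellate and bile duct, 6 neuronal, 5 macrophage and 5 cell cycle genes higher.

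In all, 1280 genes were higher and 2871 lower in W8 heart than in W8 liver (1735 and 3628 without W8 heart replicate 2). The median gene differed by -0.32, and the split was 2212 higher and 1357 lower after median centring and 1795 and 1216 after quantile normalization. A fit to the W8 heart and liver libraries alone passed 0 genes, and array weights left 474. Without W8 heart replicate 1 the limma test passed 6255 genes, and without W8 liver replicate 1 or W8 liver replicate 2 it passed 0.

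At E14 each tissue had 1 library, so the differences have no replicate check and no test. Myh6 stood at 11.5 FPKM in E14 heart and 1.54 in E14 liver, Ttn at 1.74 and 0.404, Cps1 at 0.153 and 0.306, and Gata4 at 0.697 and 0.642. All 22 sarcomere genes and 18 of 20 cardiac transcription factors were on the heart side, with medians 0.76 and 0.67 above all genes. On the same side were 27 of 28 fatty acid oxidation genes, with 0.47, a list whose median less that of all genes was -0.07 at P1 and -0.53 at W8. Plasma proteins, metabolic enzymes and transporters, and hepatocyte transcription factors lay on the liver side with -0.85, -0.69 and -0.55. So did erythroid (-0.51), cell cycle (-0.52), macrophage (-0.60), neuronal control (-0.70) and Hox lists (-0.66). The own median of the Hox list went from -0.41 to -0.12 with members at 0 set to their floor. The median gene lay 0.25 toward heart. Tissue differences at E14 correlated across genes with those at P1 at r = 0.26 and with those at W8 at -0.07 (0.02 without W8 heart replicate 2).

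**Figure D3:**
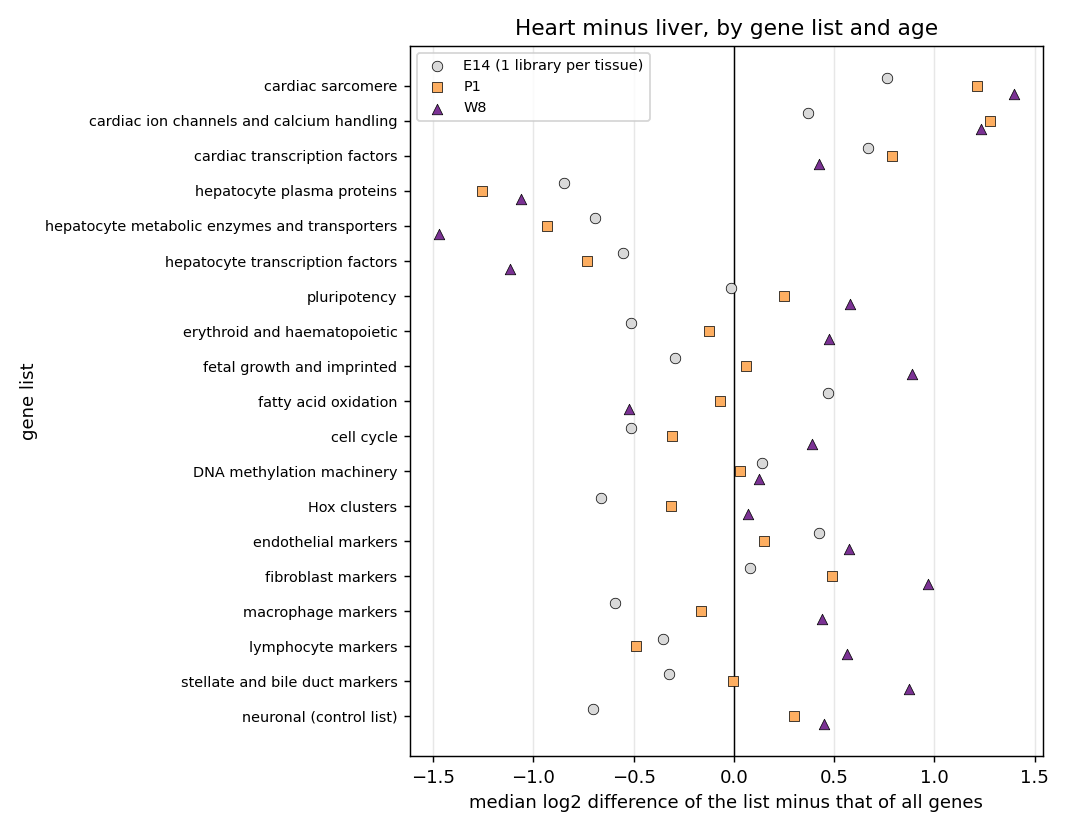
Median log2 difference of heart minus liver of each of 19 gene lists, less that of all genes (x axis), at E14, P1 and W8 (markers). Sarcomere genes lay at 0.76, 1.21 and 1.40 and hepatocyte metabolic enzymes at -0.69, -0.93 and -1.47.

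Of the genes called at both P1 and W8, 36 were higher in heart at both ages, against 4.46 for independent lists of these sizes, and 202 were lower, against 55.4. The 2 comparisons are not independent, as they take each gene's spread from 1 shared fit. The median gene also lay toward liver in both. These expectations may therefore be too low. Shared genes included Ryr2, Actn2, Tbx5 and Myocd, higher in heart, and Cps1, Ass1, Itih3 and Hnf4a, lower in heart. Another 4 were called in opposite directions. Without W8 heart replicate 2 the overlap was 570 and 1463, against 102 and 599. Then r of the 2 tissue differences across genes was 0.52 in place of 0.36. The overlap was 3 genes with a replicate block and 0 with fits to the compared groups alone. The overlap was 30 genes without P1 heart replicate 1, and 0 without P1 heart replicate 2 or any 1 of the P1 and W8 liver libraries. It was 1352 genes without W8 heart replicate 1 and 2033 without W8 heart replicate 2. At E14, 157 of the 238 genes (66.0%) had the same sign, 35 of the 36 higher and 122 of the 202 lower, while 33.5% of all genes were lower in E14 heart. Without W8 heart replicate 2 the share was 54.1% of 2033 genes, 483 of 570 higher and 617 of 1463 lower. After median centring it was 85.8% of 113 genes, when 54.4% of all genes were lower in E14 heart.

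Whether the tissue difference itself changed between P1 and W8 was tested as an interaction, in which a read format effect alike in both tissues cancels. Igf2bp1, which was 1.94 ± 0.27 further toward heart at W8, Bcl11a (1.74 ± 0.26) and the fibroblast collagen gene Col1a1 (1.68 ± 0.26), had an adjusted p of 0.0893 and did not pass (limma, n = 2 per group). Nr1i3 (-2.14 ± 0.26) and Cyp27a1 (-1.64 ± 0.24) were further toward liver, with the same adjusted p. The list of fetal growth and imprinted genes moved toward heart (0 of 20 members past the threshold; 7 adjusted over the list alone), with a median 0.92 above all genes (adjusted p = 5.64e-06, and adjusted p = 0.0769 with an estimated correlation). Erythroid genes did so with 0 of 23 (6 adjusted over the list alone) and a median of 0.88 (adjusted p = 0.000156, and adjusted p = 0.129 with an estimated correlation). Cell cycle genes followed with 0 of 29 and 0.79 (adjusted p = 7.59e-05, and adjusted p = 0.0769 with an estimated correlation). Fatty acid oxidation genes moved toward liver with 0 of 28 and a median of -0.54 (adjusted p = 7.59e-05, and adjusted p = 0.0769 with an estimated correlation). So did metabolic enzymes and transporters with 0 of 28 (4 adjusted over the list alone) and -0.53 (adjusted p = 0.0021, and adjusted p = 0.101 with an estimated correlation). Of 19 lists 10 passed, and 15 did without W8 heart replicate 2.

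The single genes past the interaction test were Ppp1r14a, an inhibitor subunit of myosin phosphatase, and Pou3f3, a transcription factor of brain and kidney, the latter named after its value was seen. Both have short bodies, of 2071 and 1062 bp. Ppp1r14a was listed at 0 in both P1 heart libraries, at 2.03 and 2.58 FPKM in P1 liver, 1.67 and 2.96 in W8 heart and 1.03 and 0.95 in W8 liver. Pou3f3 was at 0.74 and 0.87 FPKM in P1 heart, 1 read each. It was listed at 0 in P1 liver and in W8 heart, and at 0.42 and 0.23 in W8 liver. At an unadjusted p under 0.05 limma counted 2588 genes, and voom passed 1130 higher and 1055 lower. The count of 2 was unchanged without W8 heart replicate 2, and became 3929 without W8 heart replicate 1. It was 1 without P1 liver replicate 2, W8 liver replicate 1 or W8 liver replicate 2, and 0 without P1 heart replicate 1, P1 heart replicate 2 or P1 liver replicate 1.

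P1 heart against ESC asked how a newborn tissue differed from pluripotent cells; strain and culture go with this contrast. Gata4 was at 0.490 ± 0.0497 FPKM (SD, n = 2) in ESC and 1.71 ± 0.0184 in P1 heart, a log2 difference of 1.66 ± 0.14 (SE, limma, adjusted p = 0.00773). Gata6 and Mef2c, regulators of heart and muscle, rose by 1.33 ± 0.15 and 1.36 ± 0.16. Slc8a1, the sodium-calcium exchanger, rose by 2.31 ± 0.38, and Ppargc1a, a coactivator of mitochondrial genes, by 1.91 ± 0.22. Hoxd3, at 1.77 ± 0.00646 FPKM in ESC and 0.136 ± 0.00207 in P1 heart, fell by 3.13 ± 0.40 and Hoxa3 by 2.79 ± 0.32. Prdm14 and Fbxo15, genes of pluripotent cells, fell by 2.10 ± 0.34 and 1.42 ± 0.23. Pou5f1, the pluripotency factor Oct4, was at 0.00 and 0.09 FPKM in ESC and 1.43 and 0.67 in P1 heart and did not pass (adjusted p = 0.0794).

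Of 16 measured Hox genes 8 fell and none rose (13 fell when adjusted over the list alone), with a median -2.57 from that of all genes (adjusted p = 1.09e-06, and adjusted p = 0.0701 with an estimated correlation). The list's own median of -2.70 became -2.22 with members at 0 set to their floor. Hoxb9, named in that list, was listed at 0 in P1 heart, at least 2.56-fold below ESC. Sarcomere genes rose for 4 of 22 (8 adjusted over the list alone), among them Smpx (1.29 ± 0.16) and the chaperone Cryab (1.58 ± 0.29). Their median was 0.73 (adjusted p = 5.96e-06, and adjusted p = 0.208 with an estimated correlation). Ion channel genes rose for 7 of 22 (9 adjusted over the list alone), among them Kcnj5 (1.61 ± 0.26) and Kcnq1 (1.08 ± 0.18), with 0.74 (adjusted p = 1.78e-05, and adjusted p = 0.384 with an estimated correlation). Cardiac transcription factors rose for 6 and fell for 1 of 20 (8 and 2 adjusted over the list alone), with 0.59 (adjusted p = 0.000661, and adjusted p = 0.384 with an estimated correlation). In promoter windows, looked at after the data were seen, that list lay the other way, at -1.47 (adjusted p = 0.000207, and adjusted p = 0.226 with an estimated correlation). Of 28 fatty acid oxidation genes 7 rose (10, and 1 lower, adjusted over the list alone), including the fatty acid transporter Cd36 (1.70 ± 0.27), with 0.35 (adjusted p = 0.0025, and adjusted p = 0.208 with an estimated correlation). Fibroblast markers rose for 2 and fell for 1 of 18, equally adjusted over the list alone, with Dcn at 1.05 ± 0.21 and Tcf21 listed at 0 in P1 heart. The markers' median was 0.65 (adjusted p = 0.0494, and adjusted p = 0.492 with an estimated correlation). The neuronal control list fell for 7 of 21 (8 adjusted over the list alone), including the glutamate transporter Slc17a7 (-2.15 ± 0.36), with -0.58 (adjusted p = 0.00265, and adjusted p = 0.384 with an estimated correlation). The pluripotency list did not pass, with 3 of 21 lower and a median of -0.22 (adjusted p = 0.347). Its own median of -0.36 became -0.05, above the -0.13 of all genes, with the member at 0 set to its floor. In the fit without W8 heart replicate 2 members higher were 11 sarcomere, 12 ion channel, 10 cardiac transcription factor, 12 fatty acid oxidation and 5 fibroblast genes, and 11 neuronal and 11 Hox genes were lower. After median centring 9 sarcomere, 12 fatty acid oxidation and 5 fibroblast genes were higher. In the DNA methylation machinery list Uhrf1 and Dnmt1 fell by 1.37 ± 0.22 and 1.24 ± 0.27.

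In P1 heart 755 genes were higher and 958 lower than in ESC (1840 and 2628 without W8 heart replicate 2). The median gene differed by -0.13, and centring gave 1521 and 669. The limma test passed 0 genes without ESC replicate 1, 2 without ESC replicate 2, 564 without P1 heart replicate 1 and 35 without P1 heart replicate 2.

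In P1 liver against ESC, Cps1 rose by 1.64 ± 0.17 (SE; limma, adjusted p = 0.00712), from 0.235 ± 0.0412 FPKM (SD, n = 2) to 0.889 ± 0.0828. Itih3 and the copper carrier Cp rose by 1.73 ± 0.18 and 1.72 ± 0.21. Gata4 rose by 1.59 ± 0.14, while Tbx5 fell by 1.46 ± 0.25. Hoxd3 fell by 2.82 ± 0.40, and Esrrb, an orphan receptor of ESC, by 1.09 ± 0.21. Grb10 and Igf2r, imprinted regulators of growth, rose by 1.12 ± 0.14 and 1.03 ± 0.17. Xist, the RNA that silences an X chromosome, rose by 1.37 ± 0.29, and the labels give no sex.

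Metabolic enzymes and transporters rose for 8 of 28 (11 adjusted over the list alone), with a median of 0.64 (adjusted p = 0.000142, and adjusted p = 0.140 with an estimated correlation). Plasma proteins rose for 7 of 25 (9 adjusted over the list alone), including plasminogen, Plg (1.49 ± 0.27), with 0.71 (adjusted p = 0.000837, and adjusted p = 0.386 with an estimated correlation). Fatty acid oxidation genes rose for 8 and fell for 1 of 28 (12 and 1 adjusted over the list alone), with Hadhb at 1.31 ± 0.16 and Ppargc1a at 1.49 ± 0.22 against Fabp3 at -1.52 ± 0.25. The median of that list was 0.61 (adjusted p = 0.000837, and adjusted p = 0.157 with an estimated correlation). Hox genes fell for 9 of 16 (11 adjusted over the list alone), with a median of -2.49 (adjusted p = 4.63e-07, and adjusted p = 0.0622 with an estimated correlation). The list's own median went from -2.39 to -2.20 with members at their floor. The neuronal control list fell for 6 of 21 (12 adjusted over the list alone), including Slc17a7 (-2.39 ± 0.36) and Gad1 (-1.63 ± 0.30), with -0.72 (adjusted p = 1.14e-06, and adjusted p = 0.181 with an estimated correlation). Hepatocyte transcription factors, 4 of 19 higher and 1 lower, with Ppara at 0.97 ± 0.14 and Rxra at 0.99 ± 0.17, did not pass as a list (adjusted p = 0.0561). They did without W8 heart replicate 2 (adjusted p = 0.027), as did the pluripotency and ion channel lists (adjusted p = 0.0306 and 0.035). Plasma protein, metabolic and fatty acid oxidation genes then numbered 16 higher each, and 13 neuronal and 11 Hox genes were lower.

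Altogether 1400 genes were higher and 681 lower in P1 liver than in ESC (2804 and 1722 without W8 heart replicate 2). The median gene differed by 0.10, and centring gave 1225 and 854. The limma test passed 2 genes without ESC replicate 1, 4 without ESC replicate 2, 0 without P1 liver replicate 1 and 379 without P1 liver replicate 2. Zrsr1, an imprinted gene, was listed at 0 in both ESC libraries and had 4 reads over P1 heart and 8 over P1 liver. Against the ESC floor its mean was 3.40-fold higher in P1 heart and 3.77-fold in P1 liver. With so few reads neither fold is a bound.

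Genes called in both tissues against ESC numbered 511 higher, such as Gata4, Ppargc1a and Dcn, and 348 lower, such as Hoxd3 and Slc17a7. Independent lists would share 78.4 and 48.4. Both comparisons use the same ESC libraries. In 50 simulations of unchanged groups against them r across genes was 0.50, against 0.66 observed. The covariance was 0.120 against 0.406, a difference of 0.286. The simulated comparisons called a median of 0 genes, so they set no expectation for the overlap. With 1 ESC library for heart and the other for liver, a test added after the data were seen, r was 0.564 and 0.557 and the covariance 0.369 and 0.366 in the 2 arrangements. Genes were not called against 1 ESC library alone, and part of the excess overlap may come from the shared controls. The overlap of 859 was 0 without ESC replicate 1 or P1 liver replicate 1, and 2 without ESC replicate 2. It was 287 without P1 heart replicate 1, 24 without P1 heart replicate 2, 215 without P1 liver replicate 2, and 2303 without W8 heart replicate 2.

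W8 liver against P1 liver asked what differed in liver after birth, and read format goes with it. Cyp1a2, a cytochrome P450 of adult hepatocytes, rose from 0.319 ± 0.138 to 3.21 ± 0.276 FPKM (SD, n = 2), by 3.10 ± 0.35 (SE, limma, adjusted p = 0.00915). Tdo2, which opens tryptophan breakdown, rose by 2.40 ± 0.32, and Nr1i3 by 1.35 ± 0.18. Igf2bp1 fell from 1.69 ± 0.118 to 0.420 ± 0.0688 FPKM, by 1.84 ± 0.19. Meg3 fell by 1.87 ± 0.20, Hmga2 by 1.44 ± 0.15 and Lin28b, a block to let-7 processing, by 1.21 ± 0.18. Bcl11a fell by 1.87 ± 0.18 and Kit, the stem cell factor receptor, by 1.44 ± 0.14. Alb, which encodes albumin, was at 1.15 and 1.37 FPKM in P1 liver and 0.28 and 0.32 in W8 liver and did not pass (adjusted p = 0.120).

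Fetal growth and imprinted genes fell for 11 of 20 (15 adjusted over the list alone), with a median of -0.90 (adjusted p = 1.76e-06, and adjusted p = 0.120 with an estimated correlation). Erythroid genes fell for 6 of 23 (9 adjusted over the list alone), including the spectrin gene Spnb1 (-1.21 ± 0.14), with -0.79 (adjusted p = 0.000873, and adjusted p = 0.156 with an estimated correlation). Cell cycle genes fell for 6 of 29 (16 adjusted over the list alone), including Plk1 (-1.36 ± 0.20), Cdca8 (-1.50 ± 0.24) and Cdc6 (-1.16 ± 0.21). Their median was -0.58 (adjusted p = 0.000134, and adjusted p = 0.120 with an estimated correlation). Metabolic enzymes and transporters rose for 5 of 28 (10 adjusted over the list alone), including Cyp27a1 (1.06 ± 0.17) and the bile acid transporter Slco1b2 (1.21 ± 0.23). Here the median was 0.73 (adjusted p = 2.11e-09, and adjusted p = 0.0494 with an estimated correlation). Hepatocyte transcription factors, 1 of 19 higher, and fatty acid oxidation genes, 0 of 28, had medians of 0.53 and 0.37 (adjusted p = 0.00092 and 0.00224, and adjusted p = 0.133 for both with an estimated correlation). In promoter windows metabolic enzymes and fatty acid oxidation genes lay the other way, at -0.49 and -0.42 (adjusted p = 0.0162 and 0.0092, and adjusted p = 0.189 and 0.139 with an estimated correlation). Lymphocyte markers fell for 5 of 15 (7 adjusted over the list alone), including Ikzf1 (-2.34 ± 0.37) and the T cell receptor chain Cd3d (-2.22 ± 0.33), with -0.82. Fibroblast markers fell for 5 of 18 (7), including Pdgfrb (-1.55 ± 0.13), with -0.56. Endothelial markers fell for 6 of 18 (10), including Erg (-1.16 ± 0.17), with -0.31. Stellate and bile duct markers fell for 3 of 16 (5), including Ngfr (-1.60 ± 0.20), with -0.57, and macrophage markers for 5 of 16 (6), including Ptprc (-1.04 ± 0.17), with -0.30. Their adjusted p were 0.0023, 0.0023, 0.00224, 0.025 and 0.0313, and with an estimated correlation adjusted p = 0.133, 0.258, 0.230, 0.133 and 0.135. Cardiac ion channels (5 of 22 lower; 10 adjusted over the list alone) and sarcomere genes (2 of 22; 5) had medians of -0.54 and -0.42 (adjusted p = 0.00247 and 0.0148, and adjusted p = 0.429 and 0.282 with an estimated correlation). After median centring 8 fetal growth, 6 erythroid and 3 cell cycle genes were lower and 7 metabolic enzymes higher. Lower lymphocyte, fibroblast, endothelial, stellate and macrophage markers then numbered 3, 3, 2, 2 and 1. With W8 heart replicate 2 left out of the fit, 20 cell cycle, 13 ion channel, 12 erythroid, 9 sarcomere and 9 lymphocyte genes were lower and 12 metabolic enzymes higher.

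Against P1 liver 126 genes were higher and 1201 lower in W8 liver (502 and 2853 without W8 heart replicate 2). The median gene differed by -0.23. The split was 289 and 484 after median centring and 130 and 253 after quantile normalization. The limma test passed 0 genes without P1 liver replicate 1, W8 liver replicate 1 or W8 liver replicate 2 and 266 without P1 liver replicate 2.

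**Figure D4:**
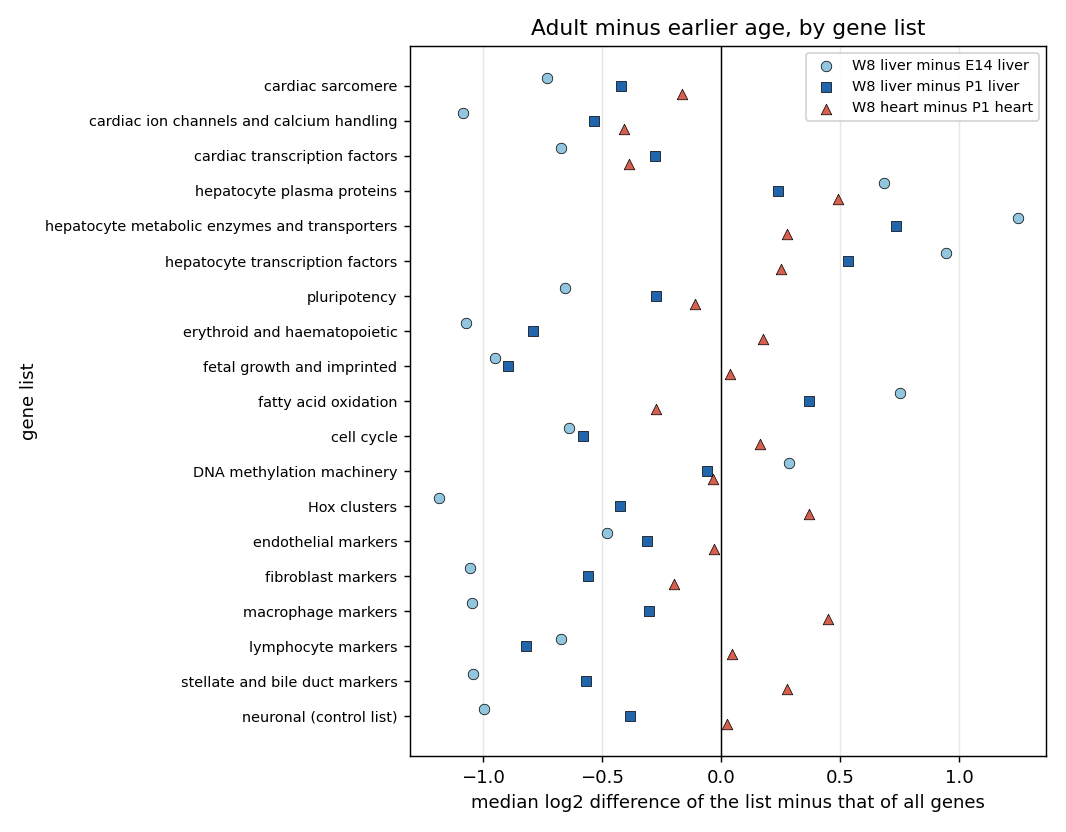
Median log2 difference of each of 19 gene lists, less that of all genes (x axis), for W8 liver minus E14 liver, W8 liver minus P1 liver and W8 heart minus P1 heart (markers). Hepatocyte metabolic enzymes lay at 1.24 and 0.73 in liver and 0.27 in heart, and fetal growth genes at -0.95 and -0.90 in liver and 0.03 in heart.

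W8 liver and E14 liver were both read from 1 end, but E14 liver had 37.1% of its reads in gene bodies and W8 liver 51.7% and 51.9%. The median gene was 0.47 higher in W8 liver. Cps1 rose from 0.306 (n = 1) to 1.66 ± 0.119 FPKM (SD, n = 2 at W8), by 2.19 ± 0.21 (SE, limma, adjusted p = 0.0117). Nr1i3 rose by 2.22 ± 0.22, Ass1 by 2.16 ± 0.19 and Cyp1a2 by 2.80 ± 0.43. Ank1, the ankyrin of red cells, fell by 1.41 ± 0.22, Bcl11a by 1.30 ± 0.22, Igf2bp1 by 1.28 ± 0.24 and Lin28b by 1.06 ± 0.22. Tet2, which makes 5hmC, Dnmt3a and Uhrf2 were higher by 0.98 ± 0.20, 1.23 ± 0.25 and 1.12 ± 0.21, and by 0.47, 0.72 and 0.61 after median centring, when none of the 21 genes of their list passed as higher. That list did not pass (adjusted p = 0.303).

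Relative to that shift, metabolic enzymes and transporters rose by a median of 1.24, with 19 of 28 members higher (25 adjusted over the list alone; adjusted p = 1.12e-07, and adjusted p = 0.0629 with an estimated correlation). Hepatocyte transcription factors rose by 0.94, with 10 of 19 (12 adjusted over the list alone; adjusted p = 0.000593, and adjusted p = 0.0781 with an estimated correlation). Fatty acid oxidation genes rose by 0.75, with 16 of 28 such as Hadh (19 adjusted over the list alone; adjusted p = 9.61e-05, and adjusted p = 0.0629 with an estimated correlation). Plasma proteins rose by 0.68, with 8 of 25 (12 adjusted over the list alone; adjusted p = 0.0456, and adjusted p = 0.428 with an estimated correlation). Erythroid genes lay at -1.07, with 6 of 23 lower (6 adjusted over the list alone; adjusted p = 2.63e-06, and adjusted p = 0.0781 with an estimated correlation). Fetal growth and imprinted genes lay at -0.95, with 5 lower and 1, Slc38a4, higher of 20 (5 and 2 adjusted over the list alone; adjusted p = 9.61e-05, and adjusted p = 0.0781 with an estimated correlation). Ion channel genes lay at -1.08, with 6 lower and 1 higher of 22 (9 and 1 adjusted over the list alone; adjusted p = 1.12e-07, and adjusted p = 0.125 with an estimated correlation). Fibroblast markers lay at -1.06, with 3 of 18 lower (3 adjusted over the list alone; adjusted p = 1.89e-06, and adjusted p = 0.0781 with an estimated correlation). Hox genes lay at -1.19, with 1 of 16 lower (0 adjusted over the list alone; adjusted p = 9.61e-05, and adjusted p = 0.0629 with an estimated correlation). Macrophage, stellate and bile duct, neuronal, sarcomere, lymphocyte, pluripotency and cell cycle lists, with 1, 2, 1, 1, 1, 0 and 1 members lower, lay at -1.05, -1.04, -0.998, -0.73, -0.68, -0.66 and -0.64. Each passed (adjusted p = 0.0274 at most), with an adjusted p between 0.0629 and 0.129 with an estimated correlation. These member counts are of unscaled values. After median centring 11 metabolic enzymes, 5 hepatocyte transcription factors, 4 fatty acid oxidation genes and 4 plasma proteins were higher. Lower were 7 erythroid, 9 fetal growth, 10 ion channel, 7 fibroblast and 1 Hox gene, and in the last 7 lists 6, 3, 3, 2, 2, 1 and 3, with none higher in any of these. With W8 heart replicate 2 left out of the fit, 14 plasma protein genes were higher, and 14 ion channel, 6 fibroblast, 5 Hox, 5 macrophage, 5 neuronal and 5 sarcomere genes lower. Cardiac transcription factors then passed as a list (adjusted p = 0.0446).

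W8 liver had 2414 genes higher and 381 lower than E14 liver (4587 and 1043 without W8 heart replicate 2). Scaling turned that split, to 467 higher and 1174 lower after median centring and 315 and 343 after quantile normalization. The limma test passed 0 genes without W8 liver replicate 1 or W8 liver replicate 2.

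In heart the same ages gave few calls. From P1 to W8, Gata6 differed by -0.55 ± 0.15, Plk1, a mitotic kinase, by -1.02 ± 0.20 and Casq2, the calcium buffer of the sarcoplasmic reticulum, by -1.17 ± 0.25, none past the test (limma, adjusted p = 0.149 each, n = 2 per group). Ion channel genes and cardiac transcription factors lay at -0.41 and -0.39 from all genes (0 of 22 and 0 of 20 members past the threshold; 15 lower and 1 higher, and 0, adjusted over the list alone). These had adjusted p = 0.00575 and 0.00651 and, with an estimated correlation, adjusted p = 0.523 and 0.372. Fatty acid oxidation genes lay at -0.27 (0 of 28; adjusted p = 0.0185, and adjusted p = 0.246 with an estimated correlation). Macrophage markers lay at 0.45 (0 of 16; adjusted p = 0.00973, and adjusted p = 0.246 with an estimated correlation). Plasma proteins at 0.49 and metabolic enzymes at 0.27 passed with all libraries (adjusted p = 0.0028 and 0.0192, and adjusted p = 0.372 and 0.246 with an estimated correlation). Without W8 heart replicate 2 their adjusted p were 0.619 and 0.059, while the neuronal control list passed (adjusted p = 0.0145). Between the W8 heart replicates themselves, plasma proteins stood 1.03 higher in replicate 2 than in replicate 1, relative to all genes, and ion channel genes at -0.70. Hox genes passed at 0.37 (0 of 16; adjusted p = 0.0235, and adjusted p = 0.246 with an estimated correlation). Their own median of 0.07 became -0.76 with members at 0 set to their floor.

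Between P1 and W8 heart 1 gene was higher, Ppp1r14a, and 1 lower, Pou3f3, and neither call held without W8 heart replicate 2. Ppp1r14a was listed at 0 in P1 heart, and its mean at W8 stood 3.77-fold above the floor. That mean rests on 27 reads over W8 heart and weighs the shallow replicate 2 equally, so 3.77 is not a bound. At an unadjusted p under 0.05 there were 3453 genes, and voom passed 5 higher and 1183 lower. Here the median gene lay at -0.30. The limma test passed 5157 genes without W8 heart replicate 1 and 0 without P1 heart replicate 1 or P1 heart replicate 2.

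Between E14 and W8 heart, Gata4 stood 0.89 ± 0.17 higher and Igf2bp1 1.16 ± 0.24 higher at W8. Myh6 stood at -1.20 ± 0.48 and Cd36 at -1.11 ± 0.33, and Fga, the fibrinogen alpha chain of liver, at 2.01 ± 0.64 (1.07 without W8 heart replicate 2), none past the test. Plasma proteins lay 0.74 above all genes (adjusted p = 1.82e-05, and adjusted p = 0.228 with an estimated correlation). Cell cycle genes lay 0.58 above (adjusted p = 0.000653, and adjusted p = 0.114 with an estimated correlation), and stellate and bile duct markers 0.51 (adjusted p = 0.00573, and adjusted p = 0.114 with an estimated correlation). Fetal growth and imprinted genes lay 0.40 above (adjusted p = 0.000115, and adjusted p = 0.120 with an estimated correlation) and metabolic enzymes 0.39 (adjusted p = 0.000767, and adjusted p = 0.114 with an estimated correlation). Macrophage markers (0.29; adjusted p = 0.0244, and adjusted p = 0.120 with an estimated correlation) and erythroid genes (0.25; adjusted p = 0.033, and adjusted p = 0.377 with an estimated correlation, and 0.275 without W8 heart replicate 2) also passed. Genes of fatty acid oxidation lay at -0.47 (adjusted p = 0.000653, and adjusted p = 0.114 with an estimated correlation). Of members, 0 passed in each of these 8 lists, and 2 fetal growth genes were higher when adjusted over the list alone. The own median of plasma proteins without W8 heart replicate 2 went from 0.64 to 0.22 and that of cell cycle genes from 0.48 to 0.26, both with an adjusted p = 0.00256. The other lists but the erythroid still passed (adjusted p = 0.00993 at most). Neuronal control, lymphocyte and fibroblast lists then passed too (adjusted p = 0.000986, 0.0109 and 0.015).

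Between E14 and W8 heart limma passed 0 genes, with or without W8 heart replicate 2, the smallest adjusted p being 0.0927. At an unadjusted p under 0.05 there were 1638 genes, voom passed 828 higher and 1447 lower, and without W8 heart replicate 1 limma passed 3615. All genes had a median difference of -0.10.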

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

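The tests of shallow depth, of even background and of a fetal or newborn liver share were planned before their results were seen, although the idea of the last came from the long gene bodies; an earlier test, for a share of adult liver, was looked at after the list values and replaced.

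The tissue by age interaction, which compares heart minus liver at W8 with heart minus liver at P1, singled out 2 genes and 10 gene lists as differing between the ages. For Ppp1r14a the fitted difference was 6.09 and for Pou3f3 -5.945 on the log2 scale; each had a group listed at 0 and short bodies with few reads, so neither value is a bound on a fold. Pou3f3, a transcription factor of brain and kidney, had 1 read in each P1 heart library. At unadjusted p under 0.05 limma counted 2588 genes.

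Lists further toward heart at W8 than at P1 were those of fetal growth and imprinted genes, whose median interaction was 0.85, stellate and bile duct markers (0.94), erythroid and haematopoietic genes (0.82), cell cycle genes (0.73), macrophage (0.58), lymphocyte (0.49), endothelial (0.28) and fibroblast markers (0.12). Fatty acid oxidation genes (-0.60) and hepatocyte metabolic enzymes and transporters (-0.59) were further toward liver. These are the lists' own medians, where that of all genes was -0.06. The camera tests of the stellate, macrophage, lymphocyte, fibroblast and endothelial lists had adjusted p of 0.00317, 0.0021, 0.00668, 0.0149 and 0.0416; with an estimated correlation these were adjusted p = 0.0769, 0.0769, 0.110, 0.423 and 0.453, and none of the 10 lists passed that way. With W8 heart replicate 2 left out 15 lists passed, the further ones being sarcomere, ion channel, hepatocyte transcription factor, Hox and neuronal lists (adjusted p = 0.0167, 0.00554, 0.00554, 0.0148 and 0.00554). With all libraries the Hox list's own median of 0.20 became -0.61 when the 7 of 16 members with a group at 0 were set to their floor. No group held more than 2 libraries, so a single library far from its group could not be tested by spread within the group.

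W8 heart replicate 2 stood apart from W8 heart replicate 1, with r = 0.871 over long bodies. Shallow depth was argued against, since parts of replicate 1 thinned to the same number of reads correlated with the rest at a median of 0.954 and at least at 0.951. Reads without enrichment spread evenly over the genome were argued against too, since on the linear scale replicate 2 was closer to a liver library, P1 liver replicate 1 (r = 0.913), than to its own replicate (r = 0.830), a difference of 0.0830 with an SE of 0.00745. A share of fetal or newborn liver material remained a candidate explanation: over 5769 bodies of 20 to 100 kb a mixture with weight 0.76 for E14 liver reached r = 0.770 against 0.669 for W8 heart replicate 1 alone (SE of the gain 0.00838), while P1 liver reached 0.752 and 0.755 and the other libraries at most 0.707. E14 liver alone reached r = 0.750 over these bodies. A part of E14 liver thinned to the depth of replicate 2 reached 0.758 with the rest of E14 liver, so 0.750 was near the limit set by depth. The P1 liver libraries alone reached 0.735 and 0.742, against 0.814 and 0.839 for their own thinned parts. Over long bodies mixtures with P1 liver reached 0.918 and 0.917 and that with E14 liver 0.916, so the 2 ages were not told apart there. An uneven background shared by replicate 2 and E14 liver, or a difference between the hearts sampled, stays open and untested.

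Some genes of liver and some of heart were high in that library. Its median gene body held 5.04 reads, so ranks of single genes may lie within counting error. Ttr, a liver plasma protein, stood at 3.44 FPKM and Alb at 1.57, above the other 11 libraries, and Tnnt2 and Myh6, sarcomere genes of heart, stood at 5.26 and 7.83, above each of the liver libraries. Relative to all genes, replicate 2 exceeded replicate 1 by 1.03 for plasma proteins, 0.52 for hepatocyte transcription factors, 0.31 for erythroid genes and 0.30 for cell cycle genes, and lay at -0.70 for ion channels and -0.66 for fibroblast markers. Cardiac transcription factors lay at -0.45, with 5 of 20 above the median gene. Sarcomere genes lay at -0.30, with 8 of 22 above it, although Myh6 itself was above W8 heart replicate 1. For metabolic enzymes and transporters replicate 2 lay at -0.03, where W8 liver exceeded W8 heart replicate 1 by 1.37. The list's own median was 1.71 higher in W8 liver than in E14 liver, where that of all genes was 0.47. Adult liver is therefore no measure of a fetal liver share for this list.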

How the results depend on the processing

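The voom, array weight, body length, promoter and shared-fit alternatives without W8 heart replicate 2 were chosen after the data were seen; the other tests were planned. Counts in this part are genes past the threshold, up and down together, against 307 in heart against liver at P1, 4151 at W8, 1713 in P1 heart against ESC, 2081 in P1 liver against ESC, 0 in W8 against E14 heart, 2795 in W8 against E14 liver, 2 in W8 against P1 heart, 1327 in W8 against P1 liver, 2 in the interaction, 238 shared by the tissue comparisons and 859 shared by the ESC comparisons; at E14 the same-sign share was 66.0%.

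Each count stayed within 1.5 times its value with no filter on low values, with genes on X and Y left out, and with a 1.5-fold minimum. It did so too with that minimum applied to differences corrected for gene length. The p-values there were uncorrected, so a count of calls could only fall.

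Median centring gave 147 in heart against liver at P1, 1641 in W8 against E14 liver, 773 in W8 against P1 liver, 113 shared by the tissue comparisons and 85.8% at E14. Quantile normalization gave 658 in W8 against E14 liver, 1 in W8 against P1 heart, 383 in W8 against P1 liver, 1 in the interaction and 86.1% at E14. These moved the medians of the libraries, which differ in their share of reads within gene bodies.

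The stricter filter, which tested fewer genes, gave 151 and 2192 in heart against liver at P1 and W8, 557 and 940 in P1 heart and P1 liver against ESC, 1 in W8 against P1 heart, 666 in W8 against P1 liver, 1 in the interaction, 121 and 301 shared by the tissue and ESC comparisons, and 57.02% at E14. A pseudocount of the median divided by 100 gave 164 in heart against liver at P1, 1 in W8 against E14 heart and 134 shared by the tissue comparisons; one equal to the median gave 825, 0 in W8 against P1 heart, 4 in the interaction and 554 shared.

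Fits to the compared groups alone, with fewer libraries to estimate the spread, gave 0 in heart against liver at P1, 0 at W8, 3372 in P1 liver against ESC, 8776 in W8 against E14 liver, 0 in W8 against P1 heart, 3446 in W8 against P1 liver and 0 shared by the tissue comparisons. Whether replicate numbers pair the samples could not be told. Deviations of replicates correlated at -0.01 to 0.04 over 10 pairs of groups. That cannot exclude pairing, since in ESC, P1 heart and P1 liver the deviations were near counting noise (chi-square per gene 1.15, 1.04 and 1.06). A replicate block gave 5 in heart against liver at P1, 0 in W8 against P1 heart, 1 in the interaction and 3 shared by the tissue comparisons.

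Without W8 heart replicate 2 in the shared fit the counts were 3021 in heart against liver at P1, 4468 and 4526 against ESC, 5630 in W8 against E14 liver, 3355 in W8 against P1 liver, and 2303 shared by the ESC comparisons. Voom on recovered reads gave 2376 and 8759 in heart against liver at P1 and W8, 3986 and 5499 against ESC, 2275 in W8 against E14 heart, 9487 in W8 against E14 liver, 1188 in W8 against P1 heart, 5188 in W8 against P1 liver, 2185 in the interaction, 1959 and 2490 shared, and 57.1% at E14. Array weights gave 1305 and 474 in heart against liver at P1 and W8, 3621 and 4582 against ESC, 7331 in W8 against E14 liver, 0 in W8 against P1 heart, 4318 in W8 against P1 liver, 0 in the interaction and 1990 shared by the ESC comparisons. Bodies of 5 kb or more gave 585 in heart against liver at P1, 0 in W8 against P1 heart, 0 in the interaction and 438 shared by the tissue comparisons. Promoter windows gave 1 in heart against liver at P1 and 1 at W8, 10 and 22 against ESC, 0 in W8 against E14 liver, 1 in W8 against P1 heart, 1 in W8 against P1 liver, 0 in the interaction, and 0 and 5 shared. Without W8 heart replicate 2 the promoter counts were 3 higher and 59 lower in heart against liver at P1, 407 and 365 in P1 heart against ESC, 1669 and 440 in P1 liver against ESC, 0 and 14 in W8 against P1 liver, and 0 in the other comparisons. Except where fewer genes or libraries were used, the cause was not tested.

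With single replicates left out, a lone library being assumed to vary like the other groups, counts ranged from 0 to 46 in heart against liver at P1, 0 to 6255 at W8, 0 to 564 and 0 to 379 in P1 heart and P1 liver against ESC, 0 to 3615 in W8 against E14 heart, 0 to 5157 in W8 against P1 heart, 0 to 266 in W8 against P1 liver and 0 to 3929 in the interaction, and were 0 both times in W8 against E14 liver; those shared ranged from 0 to 2033 and 0 to 287, and the E14 share from 51.5% to 63.3%.

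Of 171 gene list tests 90 passed by camera, 88 with the replicate block, 100 without W8 heart replicate 2, and 1 with an estimated correlation. The fry test, which sets a list against no change rather than against other genes, passed 88. Its calls fell in other comparisons, such as 10 against 16 by camera in W8 against E14 liver and 10 against 5 in P1 liver against ESC. For named genes, 184 pairs of gene and comparison were recomputed 2937 times: 2241 values kept direction and side of the threshold, 651 kept direction and no longer passed, 45 newly passed, and 0 reversed. These recomputations reused the gene-body values, and promoter windows were not among them. The 0 reversed therefore says nothing about promoters. No E14 share exists where no gene was shared, and none was made for promoters. DESeq2, edgeR's scaling and the choice among several entries of a gene, planned for counts or for repeated genes, were not run, since the values are FPKM with 1 entry per gene. Depth limits W8 heart replicate 2 most: its counting error at the median body was 44.5%, and 46.1% of its promoters had no read.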

Other observations

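Tests of cardiac 5hmC in general, of a shift between read formats of a format effect alike in both tissues and of the same liver genes against E14, and the look at promoters and gene families, were chosen after the result was seen; the test of RNA or cDNA was planned.

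Among 153 families of genes sharing a symbol stem, the cytochrome P450 family (Cyp, oxidation of drugs and sterols) was higher in W8 than P1 liver for 8 and lower for 1 of 63 measured members, with a median 0.96 above all genes (camera, adjusted p = 2.98e-12; adjusted p = 0.0296 with an estimated correlation). In W8 heart 35 Cyp genes were lower and 2 higher than in W8 liver (adjusted p = 0.000165; adjusted p = 0.299 with an estimated correlation). Collagen genes (Col) were higher in W8 heart for 15 and lower for 3 of 38 (adjusted p = 3.93e-06; adjusted p = 0.396 with an estimated correlation), and calcium channel genes (Cacna) for 7 of 13 (adjusted p = 1.24e-05; adjusted p = 0.396 with an estimated correlation). Keratin genes (Krt) were higher for 7 and lower for 1 of 37 (camera, adjusted p = 0.000909, and adjusted p = 0.352 with an estimated correlation). In W8 heart against W8 liver 28 of the 153 families passed at the preset correlation, and 0 with an estimated one.

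In promoter windows Tdgf1, a Nodal coreceptor of pluripotent cells, was listed at 0 FPKM in both ESC libraries, at 1.77 and 1.61 in P1 heart (limma, adjusted p = 0.0144) and at 1.05 and 1.83 in P1 liver (adjusted p = 0.0118). Nodal, its ligand, was at 0 and 0.13 in ESC and 2.10 and 2.04 in P1 liver (adjusted p = 0.0442). G3bp1, a stress granule protein, was listed at 0 in ESC, at 0.98 and 1.61 in P1 heart and at 2.10 and 2.25 in P1 liver. Sfi1, a centrosome protein, went the other way, from 45.0 and 46.4 in ESC to 2.94 and 1.61 in P1 heart and 4.19 and 5.06 in P1 liver. Promoter and gene body differences correlated across genes at 0.08 to 0.41. Of 171 gene list tests 90 passed in bodies and 46 in promoters, 25 of them in both and in the same direction; with an estimated correlation 1 passed in bodies and none in promoters (smallest adjusted p = 0.0688). Another 3 passed in opposite directions: cardiac transcription factors in P1 heart against ESC, and metabolic enzymes and fatty acid oxidation genes in W8 against P1 liver.

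In E14 heart some abundant cardiac transcripts exceeded every other library in gene-body values, such as Myh6 at 11.5 FPKM and Pln, a regulator of the calcium pump, at 7.07, while Ttn and Tnnt2 did not. Reads from RNA or complementary DNA are a candidate explanation, as the median excess of 26 measured genes of 86 listed as abundant transcripts was 0.13, at percentile 99.71 of 10000 matched random lists; per the labels, DNA was treated with RNase. A higher 5hmC level over cardiac loci in general stays open: cardiac transcription factors lay at -0.29 against the other heart libraries, but sarcomere genes, the list they were set against, showed no excess there either (-0.01). A higher level at highly transcribed genes alone stays open and untested, as does age.

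W8 liver had many more genes lower than higher than P1 liver, 1201 and 126, a pattern that goes with read format. A shift of all values between the formats stays open as a cause of much of it: after median centring 484 were lower and 289 higher, 1.67 for each, close to the bound of 1.5 that was set after the result. A gene-specific effect of format alike in both tissues was argued against: the median change of the 1201 genes in heart, W8 replicate 1 against P1, was 0.00572 relative to all genes, and -0.03 with W8 replicate 2, against -0.89 in liver. The 1201 genes lowest in 1 W8 liver library against P1 lay, in the other W8 library against E14 liver (n = 1, the same format), at -1.03 and -0.97 relative to all genes, and 95.8% and 95.3% were lower, which counts against format for these genes but cannot show a shift of all values. Age stays open and untested, and the loss of cell types such as blood-forming cells, whose list fell in the same comparison (adjusted p = 0.000873; adjusted p = 0.156 with an estimated correlation), could not be separated from change within hepatocytes.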
